A study of Rattus norvegicus with 12 samples.

How the data were processed

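The data are 12 Affymetrix arrays of RNA from rat Sertoli cells, the somatic cells of the seminiferous tubule that nurse the developing germ cells. Per the labels' protocols, testes of 9-day-old rats were digested, the isolated cells were kept for 24 h in medium with fetal bovine serum, and the cultures then received 0.1 mM of a compound abbreviated as MBP or no MBP for another 24 h before RNA extraction. The abbreviation is not spelled out in the labels. RNA of 3 control and 3 MBP samples was hybridised to a whole-transcript gene array, and RNA of 3 control and 3 MBP samples to a microRNA array. Samples in each group carry the numbers 1 to 3. Nothing in the labels says whether the numbers stand for separate animals, isolations or dishes, so p-values measure the spread between these samples, which may in part be technical.

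The deposited value tables of both array types hold log2 signals, 1 value per probe set and array, which the authors normalized across the 6 arrays of a type. Quartiles were nearly alike on all arrays of a type, and the unit was settled from the range of the values. The submitters' processing notes name MAS5 with no role or version. The header of the authors' annotated gene array table names its own signal columns as RMA signals, so the method behind the values used here is not given in the sources used here. That table has 6 signal columns whose names match no sample label. They were not used in any step, and only the table's annotation text was read. The 2 platforms were normalized apart and were never pooled.

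The gene array table holds 29214 probe sets, of which the 27342 of the annotation's main category were tested. Array controls (21 and 45 probe sets), 399 exon and 1153 intron normalization controls and 254 unmapped probe sets were left out. Gene names were updated through a RefSeq gene table of assembly GRCr8, used for names only. It named 15109 main probe sets through a RefSeq accession and 3173 through a symbol or synonym, and 1530 kept the symbol of the file. In all, 19812 probe sets had 1 symbol, 2167 had several and 5363 had none, and no gene was named from a probe set with several. Positions are those of Ensembl transcripts on Rnor_5.0 as the annotation text gives them. The microRNA table holds 1277 probe sets, of which 728 mature and 490 stem-loop probe sets were tested and 59 controls were left out. The table gives mature probe sets by identifier alone and pairs them with no name. For stem-loops, names came from the gene array's annotation text, which covered 318 of 449 accessions.

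Each comparison was MBP minus control, fitted per platform with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on the log2 values, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Intervals are 95% intervals from the same fit. For 22 gene lists, limma's camera with a preset correlation of 0.01 was run on 18287 genes, each represented by its probe set of highest mean over the 6 arrays. Probe sets of a gene can disagree under this rule. The 2 of Fshr did, at mean log2 signals of 2.60 and 10.62. The brighter one, which the rule takes, lies outside the gene and is annotated with GAPDH transcripts as well, so its signal may not be that of Fshr. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. The lists, the tests, the main fits and the alternatives were fixed before the data were examined. The 13 microRNA lists were meant for mature probe sets and could not be run on them without names. Instead, the 8 lists with 3 or more named stem-loops were tested on stem-loop probe sets, which was chosen after seeing the data.

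Named genes followed a fixed rule. In each direction it takes the 10 largest changes among probe sets with an adjusted p under 0.05, 1 symbol and groups that do not overlap. Where fewer pass, it takes those that pass and then those of smallest unadjusted p up to 5, said not to have passed. For each list it takes the 2 members of largest rise and the 2 of largest fall that pass, or else the 2 of smallest p. Predicted loci are counted and not named. Genes of other parts of the text, given for their level or their difference between sample numbers, were chosen after their values were seen.

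Sample numbers were checked for pairing before the fits were compared. The deviations of same-numbered control and MBP samples from their group means correlated across gene array probe sets at 0.567, 0.603 and 0.779, against -0.535 to 0.048 for samples of different numbers. On the microRNA arrays they correlated at 0.332, 0.372 and 0.276, against -0.263 to -0.043. Every same-numbered correlation exceeded 0.1, so the numbers pair the samples. The basis of this pairing is the data, since the labels give only a shared number. The fit with the replicate number as a block is given beside a result where it changes a call.

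Arrays have no read depth, and their number limits the precision. As a measure of signal over background, chosen after seeing the data, a probe set counted as above background where its signal exceeded the 95th percentile of the intron control probe sets of that array, which lay between 5.67 and 6.20. By this measure 24.3% to 29.9% of main probe sets per array and 6341 on all 6 gene arrays were above background. A probe set below that level can still report RNA, but no fold is given for it, and no change is read from a log2 difference of it. The microRNA table holds no comparable control set, so no such limit was set there.

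The scripts were tested on simulated data drawn with the spread of these arrays. On the gene array, with 200 of 27342 probe sets changed, the fit without the block recovered 22% of the 1.5-fold, 68% of the 2-fold and 98% of the 4-fold changes, and the fit with the block 50%, 94% and 100%. On the microRNA array, with 40 of 1218 probe sets changed, the fit without the block recovered 0%, 60% and 80%, and the fit with the block 10%, 80% and 100%.

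Alternatives covered quantile normalization, median centring, a level filter, a trended and robust variance, array weights, the replicate block, leaving out each array, looser and stricter thresholds, and the units tested. An alternative pseudocount had no use because the tables were already on the log2 scale. The alternative of taking per-array values from the annotated table was not run because its signal columns match no sample. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.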

Results

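Messenger RNA and microRNA were profiled in cultured Sertoli cells of 9-day-old rats after 24 h with 0.1 mM MBP or without it. The gene array and the microRNA array each had 3 control and 3 MBP samples, so 12 arrays were used in all. The design asks which genes and which microRNAs differ between MBP and control cultures. Median log2 signals of the gene arrays ranged from 3.84 to 3.89, and 6647 to 8178 of the 27342 tested probe sets per array lay above the background of the intron controls. On the microRNA arrays the median log2 signal of mature probe sets ranged from 1.01 to 1.18, and 141 to 154 of the 728 mature probe sets exceeded a log2 signal of 6.

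Some genes listed as Sertoli cell markers and most of those listed for contractile and connective tissue cells were above background. Which cells made these transcripts was not tested. Of 30 measured Sertoli cell markers, 6 were above background on all 6 arrays, or 5 without the FSH receptor gene Fshr, whose bright probe set lies outside the gene and is annotated with GAPDH transcripts as well. Among them were the transcription factors Wt1, at a mean log2 signal of 6.98 ± 0.06 (SD, n = 3) in control and 7.002 ± 0.07 in MBP arrays, and Gata4, at 8.11 ± 0.11 and 8.02 ± 0.09. The secreted chaperone Clu stood at 9.28 ± 0.44 and 9.24 ± 0.49, and the activin subunit Inhba at 9.62 ± 0.47 and 9.56 ± 0.52. The anti-Müllerian hormone gene Amh, the tight junction gene Cldn11, the inhibin subunit Inha and the hedgehog ligand Dhh were below background on every array. Of 19 markers of peritubular myoid cells, the contractile cells around the tubule, and of fibroblasts, 15 were above background, among them Tagln, Actg2, Myh11 and Col1a1. Of 13 Leydig cell markers, 2 were above background. One was Star, which carries cholesterol into mitochondria, at 11.01 in both groups, while the steroidogenic enzymes Cyp11a1 and Cyp17a1 were below background. Only 1 of 17 germ cell markers, 1 of 17 macrophage and leukocyte markers, 0 of 12 endothelial markers and 0 of 6 red cell genes were above background.

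**Figure D1:**
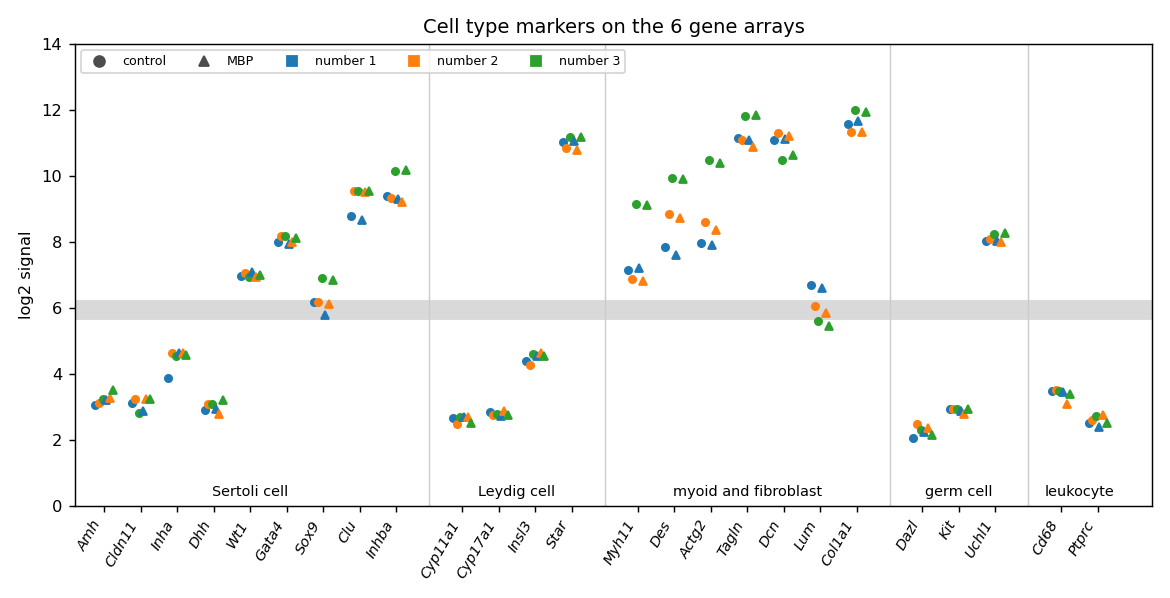
Log2 signals (vertical axis) of cell type markers on the 6 gene arrays, with circles for control, triangles for MBP and 1 colour per sample number. The grey band spans the 95th percentiles of the intron controls, 5.67 to 6.20. Control and MBP arrays of a number lie close together, and the contractile genes Myh11, Des and Actg2 are higher in both arrays numbered 3.

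MBP left the messenger RNA profile close to that of the controls. No probe set of the 27342 passed the test, and none differed by 2-fold or more between the group means. Even the genes of smallest p differed little and were dim. The olfactory receptor gene Or1j15b (chromosome 3, 21197583 to 21198512, Rnor_5.0) had mean log2 signals of 2.19 in control and 1.79 in MBP arrays, with an unadjusted limma p of 0.000425. Below it came another olfactory receptor gene, Or4p20b, at 2.21 and 1.84, the mitochondrial tRNA modification gene Mto1, at 3.66 and 3.39, Tent5c, which lengthens poly(A) tails, at 4.58 and 4.31, and Phykpl, at 5.12 and 4.86. In the other direction stood Tektip1, at 3.92 in control and 4.19 in MBP arrays, the RNA-binding gene Fxr1, at 4.59 and 5.01, Tigd3, at 3.88 and 4.29, Testin, which encodes a protein that Sertoli cells secrete, at 3.04 and 3.27, and Amer1, a regulator of Wnt signalling, at 4.85 and 5.18. All 10 of these genes lay below background on at least 1 array, so no fold is given, and each had an adjusted p of 1.

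The smallest adjusted p over all probe sets was 1 in limma, and at an unadjusted p under 0.05 there were 351 probe sets, 221 higher and 130 lower with MBP, where chance gives 1367 for arrays that are not paired. The 3 other splits of the arrays that part all pairs of same-numbered samples gave 281, 310 and 311. After median centring of each array the counts were 135 higher and 239 lower, so no direction is drawn from them. Predicted loci made up 20 of the 351, and 116 had several symbols or none. Groups did not overlap for 3.43% of probe sets, against the 10% that chance gives for arrays that are not paired and 2.87%, 2.96% and 3.07% in those 3 splits. With the replicate number as a block, the count stayed at 0, with a smallest adjusted p of 0.865 and 1255 probe sets at an unadjusted p under 0.05. The same 3 other splits gave 1075, 1047 and 1028 with the block. Fitted with the block on the 6341 probe sets above background alone, 427 had an unadjusted limma p under 0.05, 99 higher and 328 lower, where chance gives 317. None of them passed (smallest adjusted p = 0.656). In the blocked fit of all probe sets, 192 of the same 6341 had an unadjusted limma p under 0.05, 50 higher and 142 lower. The excess over chance therefore depends on which probe sets were fitted. The 95% interval of the difference excluded a 2-fold change for 97.4% of the 6341 probe sets above background without the block and 100% of them with it.

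**Figure D2:**
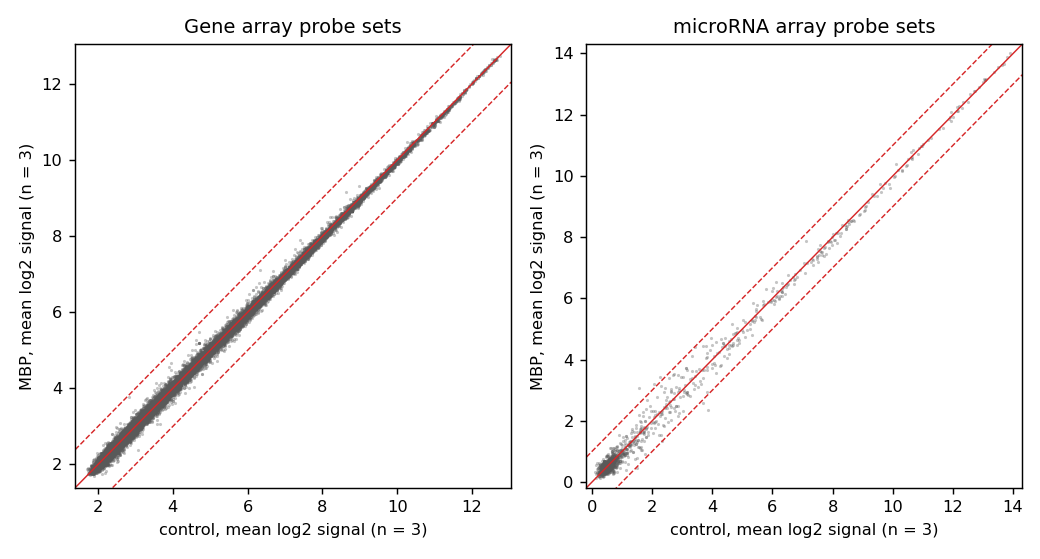
Mean log2 signal of each probe set in the 3 control arrays (horizontal axis) against the 3 MBP arrays (vertical axis), for the gene array and the microRNA array. The solid line marks equality and the dashed lines 2-fold differences. All gene array probe sets lie between the dashed lines, and 6 microRNA array probe sets lie outside them.

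Gene groups were tested through 22 lists, and the 2 of smallest camera p that were lower with MBP were genes of the mitochondrial respiratory chain, which carries out oxidative phosphorylation, and of the ubiquitin and proteasome system, which degrades proteins. Of 31 respiratory chain genes, 29 were lower with MBP, by a median log2 difference of -0.073, and the median was below 0 in each pair of same-numbered samples (-0.091, -0.073 and -0.068). Leaving out MBP array 3 turned the median to 0.017, and leaving out control array 2 brought it to -0.0081. Leaving out 1 array leaves unequal sample numbers in the groups, and the mean log2 signal of the list was 7.70 in number 3 against 7.96 and 8.02. Leaving out both arrays of number 1, 2 or 3, chosen after seeing the data, gave medians of -0.060, -0.081 and -0.074. Cox6c, a subunit of complex IV whose probe set also matches a processed pseudogene, had log2 signals of 9.88 in control and 9.72 in MBP arrays, and the complex I subunit Ndufs4 (chromosome 2, 65403183 to 65515260) 7.73 and 7.54. Of 32 ubiquitin and proteasome genes, 27 were lower, by a median of -0.051, with pair medians of -0.066, -0.085 and -0.065. The median was -0.0074 without MBP array 3, -0.016 without control array 2 and -0.113 without control array 3. With both arrays of number 1, 2 or 3 left out it was -0.062, -0.037 and -0.057. The ubiquitin ligase Itch had log2 signals of 6.92 and 6.79, and the proteasome ATPase Psmc5 6.88 and 6.74.

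Neither list passed without the block, at adjusted camera p-values of 0.0833 and 0.0949. With the replicate number as a block, 4 lists fell below the threshold. These were the respiratory chain (adjusted p = 2.18e-05), ubiquitin and proteasome genes (adjusted p = 0.0144), the myoid and fibroblast markers (adjusted p = 0.0455, 16 of 19 lower, median -0.062) and cell cycle genes (adjusted p = 0.0455, 32 of 43 lower, median -0.034). The myoid and fibroblast list had pair medians of 0.018, -0.093 and -0.052 and the cell cycle list -0.016, -0.094 and -0.015. Among genes above background the blocked adjusted p was 0.272 and 0.316 for these 2 lists and 0.271 for the proteasome list. Their medians there were no smaller in size, at -0.075, -0.045 and -0.058. After removal of a trend with signal level the adjusted p was 0.540, 0.607 and 0.540, with medians nearer to no difference, at -0.029, -0.0060 and -0.023. None of the 4 held with an estimated correlation in the blocked fit, where the respiratory chain had an adjusted p = 0.772 and the other 3 an adjusted p = 0.910, nor with blocked fry, where the smallest adjusted p was 0.572. For the respiratory chain the estimated correlation was 0.0051, below the preset 0.01, so its loss does not come from a larger correlation. It was above the preset for the proteasome (0.019), cell cycle (0.112) and myoid and fibroblast (0.230) lists. A larger correlation may therefore add to the loss of these 3 calls. Camera with an estimated correlation rests on the 2 residual degrees of freedom of the blocked fit and has little power. Its outcome therefore does not decide whether these lists moved, and the 4 calls hold only at the preset correlation. The list calls also changed when single arrays were left out, which leaves unequal sample numbers in the groups. Such fits mix differences between sample numbers with the difference between MBP and control. In the fit without the block, leaving out control array 3 gave 5 passing lists: the respiratory chain (adjusted p = 7.10e-08), proteasome (0.000122), PPAR (0.0105) and NRF2 (0.0368) lists lower and the endothelial list (0.0368) higher. Without MBP array 1 the respiratory chain and proteasome lists (both 0.0117) and the cell cycle list (0.0245) passed. Without MBP array 2 the respiratory chain (0.000719) and proteasome (0.0496) lists passed, and without MBP array 3 the cholesterol (0.000687) and ER stress (0.0234) lists. Leaving out control array 1 or control array 2 gave 0. With the block and both arrays of number 1, 2 or 3 left out, the respiratory chain passed each time at the preset correlation (camera, adjusted p = 0.0178, 0.000991 and 2.79e-05). After quantile normalization only the respiratory chain passed with the block, at an adjusted p of 0.0154 and a median of -0.044.

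**Figure D3:**
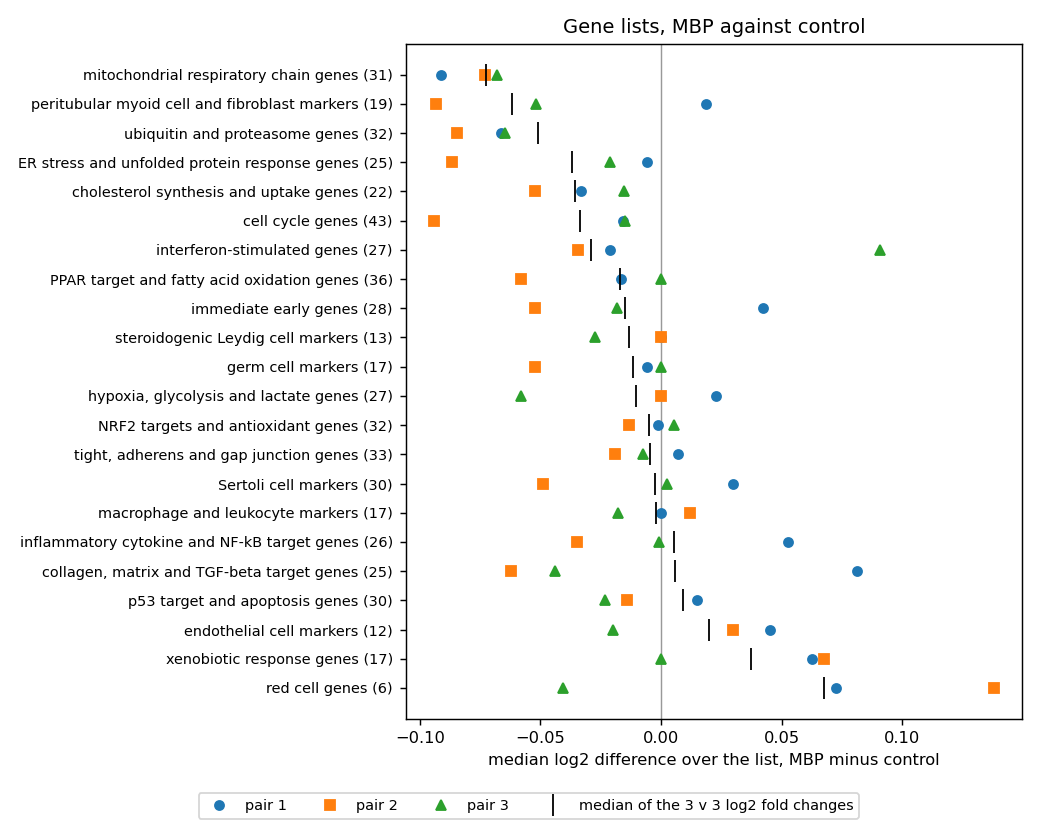
Median log2 difference between MBP and control (horizontal axis) over the measured members of each gene list, with the number of members in brackets. Coloured symbols give the 3 pairs of same-numbered samples and black ticks the difference of group means. Respiratory chain genes and ubiquitin and proteasome genes lie below 0 in all 3 pairs, as do cholesterol, ER stress and cell cycle genes.

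Individual genes of the cell cycle and stromal lists did not pass. Cdc20, an activator of the anaphase-promoting complex (chromosome 5, 141050192 to 141054395), had log2 signals of 7.32 ± 0.19 (SD, n = 3) in control and 7.05 ± 0.25 in MBP arrays, and the ubiquitin-conjugating gene Ube2c 8.08 and 7.88. The proliferation marker Mki67 was at 9.08 and 9.09. Among the stromal markers, Thy1 had 7.48 and 7.33 and Pdgfrb 7.63 and 7.57. No member of any of the 22 lists had an adjusted p under 0.05 over all probe sets, and the count was 0 in every list when adjusted over the list alone, without and with the block.

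Lists of genes tied to Sertoli cell function showed no joint shift. Only 6 of 30 Sertoli markers, Fshr among them, and 13 of 33 junction genes were above background on all 6 arrays. For most members of these lists a lack of response is therefore not shown. Of 30 Sertoli markers, 15 were higher and 15 lower (median -0.0025, camera, adjusted p = 0.965), and those of smallest p were the transcription factor Etv5, at log2 signals of 4.70 and 4.56, and Cst12, at 2.32 and 2.17. Of 33 genes of tight, adherens and gap junctions, which form the blood-testis barrier, 15 were higher (median -0.0045, adjusted p = 0.965). Cldn4 was at 3.55 in control and 3.78 in MBP arrays, and Tjp3 at 3.23 and 3.32, all below background. Of 27 hypoxia, glycolysis and lactate genes, 9 were higher (median -0.010, adjusted p = 0.965), with the glycolytic enzyme Pgk1 at 9.98 and 9.90 and Pfkm at 4.76 and 4.90. Of 25 collagen, matrix and TGF-beta target genes, 13 were higher (median 0.0057, adjusted p = 0.965), with Smad7 at 5.96 and 5.87 and Col18a1 at 4.39 and 4.52.

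Lists for lipid and xenobiotic responses did not pass with all arrays, without or with the block. Of 36 PPAR targets and fatty acid oxidation genes, 16 were higher (median -0.017, camera, adjusted p = 0.965). Its 2 members of smallest p, the thioesterase Acot1 and the kinase Pdk4, were below background, at 2.23 and 2.496 and at 3.22 and 3.42 in control and MBP arrays. Of 22 cholesterol synthesis and uptake genes, 6 were higher (median -0.036, adjusted p = 0.965), with Ebp at 7.02 and 6.89 and Pmvk at 5.59 and 5.68. Of 17 xenobiotic response genes, 12 were higher (median 0.037, adjusted p = 0.568), with the nuclear receptor Nr1i3 at 2.65 and 2.74 and Cyp3a9 at 2.05 and 2.15. Only 3 of these 17 were above background on all 6 arrays. The steroidogenic markers had 5 of 13 members higher (median -0.013, adjusted p = 0.965). Insl3 was at 4.41 and 4.57, and Lhcgr at 2.41 and 2.46. Star was at 11.01 in both groups, with a log2 difference of -0.00081.

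Stress and death programmes were likewise without a passing list with all arrays. NRF2 targets and antioxidant genes had 14 of 32 members higher (median -0.0051, camera, adjusted p = 0.965), with Gpx2 at 2.89 and 3.01 and Osgin1 at 3.99 and 3.91. Genes of ER stress and the unfolded protein response had 6 of 25 higher (median -0.037, adjusted p = 0.728), with Ppp1r15a at 6.09 and 5.88 and Creld2 at 6.47 and 6.29. For p53 targets and apoptosis genes 17 of 30 were higher (median 0.0089, adjusted p = 0.965), with the death receptor Tnfrsf10b at 7.16 and 6.92 and Casp8 at 4.79 and 4.88. Inflammatory cytokines and NF-kB targets had 15 of 26 higher (median 0.0052, adjusted p = 0.965), with Relb at 5.21 and 5.34 and Il1b at 3.31 and 3.42. Immediate early genes had 13 of 28 higher (median -0.015, adjusted p = 0.965), with Nr4a2 at 5.81 and 5.56 and Fosb at 3.63 and 3.75. Interferon-stimulated genes had 12 of 27 higher (median -0.029, adjusted p = 0.965), with Ifit3 at 2.27 and 2.40 and Usp18 at 2.26 and 2.11. Only 2 of these 27 were above background on all 6 arrays.

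Markers of germ, immune, endothelial and red cells gave no passing list with all arrays, without or with the block. Germ cell markers had 6 of 17 members higher (median -0.012, camera, adjusted p = 0.728), with Dnd1 at 4.08 and 3.90 and Zbtb16 at 3.55 and 3.36. Macrophage and leukocyte markers had 8 of 17 higher (median -0.0020, adjusted p = 0.965), with Cd68 at 3.48 and 3.29 and C1qa at 2.69 and 2.79. Endothelial markers had 7 of 12 higher (median 0.020, adjusted p = 0.965), with Emcn at 2.81 and 2.96 and Sox17 at 3.46 and 3.54. Red cell genes had 5 of 6 higher (median 0.068, adjusted p = 0.359), with Slc4a1 at 2.89 and 2.97 and Hbb at 4.43 and 4.60. Median and camera direction differed in sign for the Sertoli, Leydig, junction and NRF2 lists, and the mean differed in sign from both of them for the p53 and collagen lists, all of them near 0. With an estimated correlation in the fit without the block every list had an adjusted p = 0.988, and with fry 0.997.

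No microRNA array probe set passed the test either. Of 1218 mature and stem-loop probe sets, 46 had an unadjusted p under 0.05 (22 higher, 24 lower, against 60.9 from chance for arrays that are not paired), and the smallest adjusted limma p was 0.421. The mature probe set MIMAT0017904 had a mean log2 signal of 1.58 ± 0.44 (SD, n = 3) in control and 3.07 ± 0.21 in MBP arrays, and MIMAT0003115 2.06 ± 0.30 and 3.21 ± 0.23. In the other direction, MIMAT0000863 stood at 1.19 ± 0.11 and 0.60 ± 0.11, and MIMAT0003121 at 0.93 ± 0.02 and 0.47 ± 0.26. All 4 lay at the low end of the scale, and their adjusted p-values were 0.421, 0.421, 0.764 and 0.993. Among named stem-loops, let-7c-2 was at 0.72 in control and 0.26 in MBP arrays, miR-344a-2 at 1.503 and 0.46, and miR-3576 at 0.85 and 0.49, each with an adjusted p of 0.993. With the block the count stayed at 0, with 58 probe sets at an unadjusted p under 0.05 and a smallest adjusted p of 0.495. Leaving out control array 1 gave 3 calls, MIMAT0017904 (adjusted p = 0.0379, log2 difference 1.73) and 2 other mature probe sets, 1 higher (adjusted p = 0.0216) and 1 lower (adjusted p = 0.0228), and leaving out any of the other 5 arrays gave 0. The 95% interval excluded a 2-fold change for 88.6% of probe sets, many of them at the bottom of the scale.

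Among microRNA families the stem-loop probe sets showed no shift. The let-7 family had 5 of 10 stem-loops higher (median log2 difference -0.018, camera, adjusted p = 0.785), and the miR-17-92 cluster with its paralogs 4 of 10 (median -0.045, adjusted p = 0.785). The miR-34 and miR-449 family had 4 of 5 higher (median 0.063, adjusted p = 0.778), the miR-29 family 1 of 4 (median -0.11, adjusted p = 0.778) and the miR-200 family 0 of 3 (median -0.086, adjusted p = 0.785). The miR-30 family had 3 of 6 higher (median 0.0076, adjusted p = 0.927), the miR-181 family 3 of 6 (median 0.050, adjusted p = 0.778) and the Dlk1-Dio3 cluster 2 of 4 (median -0.032, adjusted p = 0.927). Median stem-loop signals of these families lay between 0.50 and 1.18, at the bottom of the scale. The other 5 lists, of inflammation-linked, smooth muscle, endothelial and blood cell, X-linked testis cluster and hypoxia microRNAs, had fewer than 3 named stem-loops and were not tested.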

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

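The count of changed messenger RNA probe sets was 0 under quantile normalization, median centring, the level filter, trended and robust variances, array weights, 1-symbol probe sets, the replicate block and every array left out. The microRNA count was 0 under the same settings, with mature probe sets alone in place of 1-symbol probe sets, except that leaving out each array in turn gave 0 to 3. Requiring only groups of 3 apart and a 1.5-fold difference gave 7 messenger RNA and 13 microRNA probe sets, and an unadjusted p under 0.05 with a 2-fold difference gave 0 and 5. Of these 5, 2 were higher (MIMAT0017904 and MIMAT0003115) and 3 lower (the stem-loop of miR-344a-2 and 2 mature probe sets without names). The looser criteria account for these counts by construction. Pairing the arrays in a replicate block moved the number of passing gene lists from 0 to 4 and changed no other call. Leaving out each array in turn gave 0 to 5 passing lists, and fry and an estimated correlation gave 0.

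The following alternatives were chosen after seeing the data. With the block, 1 list passed among genes above background only and 1 after quantile normalization, the respiratory chain in both. Leaving out both arrays of number 1, 2 or 3 gave 3, 1 and 3 passing lists with the block, and the respiratory chain was among them each time (adjusted p = 0.0178, 0.000991 and 2.79e-05). These calls use the preset correlation, and with all arrays the blocked call was lost at an estimated correlation (adjusted p = 0.772) and with fry (adjusted p = 0.572). Camera with an estimated correlation had little power there, on 2 residual degrees of freedom. Blocked fits with trended and robust variances, probe sets above background and the removal of both arrays of a number gave 0 messenger RNA probe sets, and the microRNA count was 0 in the same alternatives that were run there. The stem-loop list count was 0 without and with the block.

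Medians of lists that had not passed changed sign in some settings. Quantile normalization turned the Leydig (0.0040), junction (0.0038), NRF2 (0.020) and hypoxia (0.0036) lists above 0, without and with the block. Members above the median level turned the endothelial list (-0.024), and genes above background turned the p53 list (-0.026), both below 0. Leaving out 1 array sets unequal sample numbers against each other, and list medians then ranged widely. They ranged from -0.180 to 0.017 for the respiratory chain, -0.218 to 0.185 for myoid and fibroblast markers, -0.185 to 0.105 for cholesterol genes, -0.142 to 0.085 for NRF2 targets, -0.119 to 0.062 for PPAR targets and -0.110 to 0.025 for the cell cycle. The range was -0.106 to 0.124 for collagen and matrix genes, -0.104 to 0.122 for inflammatory genes, -0.092 to 0.035 for ER stress, -0.063 to 0.076 for junctions, -0.062 to 0.111 for endothelial markers and -0.069 to 0.0026 for germ cell markers. It was -0.058 to 0.038 for immediate early genes, -0.055 to 0.026 for interferon-stimulated genes, -0.041 to 0.020 for hypoxia genes, -0.034 to 0.020 for leukocyte markers, -0.033 to 0.017 for Leydig markers, -0.011 to 0.027 for Sertoli markers and -0.0092 to 0.026 for p53 targets. Among single genes, the log2 difference ranged from -0.021 to 0.21 for Col18a1, -0.18 to 0.023 for Pdgfrb and -0.34 to 0.037 for Thy1. Col18a1 was below background, so no change is read from its range. No named gene passed under any alternative, and of the named microRNA probe sets only MIMAT0017904 did, without control array 1. Dim signals limit these results, since 6341 of 27342 probe sets were above background on all 6 gene arrays.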

Other observations

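All tests in this part were chosen after the results were seen, except the splits of the microRNA arrays. The samples differed far more by number than by treatment. With the group in the model, 2630 of 27342 gene array probe sets differed between the numbers 1, 2 and 3 at an adjusted limma p under 0.05, and 402 of these spanned more than 2-fold. Both gene arrays numbered 3 also had the highest background limits, 6.20 and 6.18 against 5.67 to 5.88. They had the fewest probe sets above background, 6647 and 6661 against 7568 to 8178. Array quality thus differed along with the sample number, and it cannot be told apart from a difference between the samples. Samples numbered 3 had the highest signals of smooth muscle genes in both arms. Myh11, the smooth muscle myosin heavy chain, was at a log2 signal of 9.16 in control 3 and 9.11 in MBP 3, against 6.81 to 7.21 in the other 4 arrays, and Actg2 was at 10.49 and 10.40 against 7.89 to 8.60. The growth factor Tgfb3 (9.17 and 9.08 against 6.20 to 6.50) and the integrin Itga11 (8.99 and 8.96 against 5.98 to 6.43) went the same way. Samples numbered 2 had the highest signals of the prostaglandin E synthase Ptges (10.18 and 10.23) and the matrix metalloproteinase Mmp3 (9.28 and 9.33). Ptges was at 7.25 and 7.26 in number 3, and the glutathione transferase Mgst1 was at 8.23 and 8.18 in number 3 against 10.02 to 10.46 elsewhere. On the microRNA array 0 of 1218 probe sets differed between the numbers at an adjusted p under 0.05, and 126 did at an unadjusted p under 0.05.

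Pair-wise responses to MBP resembled each other little across single probe sets, although the medians of some lists, such as the respiratory chain, were below 0 in each pair. Across gene array probe sets, which are not independent replicates, the log2 differences of 2 pairs correlated at 0.025, 0.031 and 0.037, and across the 6341 probe sets above background at -0.031, 0.134 and 0.019. On the microRNA array the correlations were -0.079, 0.055 and 0.089.

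The 6 arrays of a type make 10 splits into groups of 3, too few for a share under 0.05. For messenger RNA the real count of 0 was also the highest count of the other splits (0), so all 10 splits gave a count as large, and the same held for microRNA (0, 10 of 10) and for stem-loop lists (0, 10 of 10). For gene lists without the block the real count was 0, all 10 splits gave as many, and the highest other count was 11, in a split with both samples numbered 3 on the same side. The splits that part fewer pairs gave 2 to 11 passing lists, which points to the structure of the sample numbers. Of the 4 splits that part all 3 pairs, 1 gave as many passing lists with the block as the real 4, the real one itself, and the highest other count was 1.

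Respiratory chain genes were lower with MBP in all 3 pairs, and a technical trend of differences with signal level is a candidate explanation, since bright probe sets were on the whole slightly lower with MBP (median log2 difference -0.030 above background). The median of the respiratory chain list lay at percentile 0.06 of 10000 random lists matched on level, whose own median was -0.029. Members of the random lists were drawn independently of each other, unlike genes that may move together. The percentile alone therefore does not decide against a trend with level. After such a trend was removed within each pair, the list kept a median of -0.041 with 24 of 31 genes lower and a blocked camera adjusted p of 0.0155 at the preset correlation, which argues against the trend as the whole cause, but the adjusted p was 0.842 at an estimated correlation and 0.620 with fry (0.772 and 0.572 before the removal). For ubiquitin and proteasome genes the percentile was 4, and removing the trend with signal level brought the median from -0.051 to -0.023 and the adjusted p to 0.540, so the trend stays open there. Members may also drift together between dishes: the estimated correlations in the blocked fit were 0.0051 and 0.019, but they rest on 2 residual degrees of freedom, and this explanation cannot be told apart from an effect of MBP on these genes, which stays untested.

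Contractile genes were higher in the samples numbered 3 of both arms, 7 of the 8 in the stromal list (Actg2, Cnn1, Des, Lmod1, Myh11, Mylk and Tagln, without Synpo2). Lmod1 was below background in the samples numbered 1 and 2, and Synpo2 on all 6 arrays. No size of change is read for either, though the medians of the 8 include them. Scaling left in the values does not account for the higher contractile signals, since quartiles were nearly alike on all arrays. Quantile normalization could therefore change little, and the median difference was 1.497 log2 after it and 1.48 before. The higher background of the arrays numbered 3 was not tested as a cause. If a larger share of all stromal cells raised every member alike, the other 11 members of the list would rise by about as much. Their median difference was 0.23, short of the contractile genes by 1.25 with an SD of 0.69. The 8 contractile genes were set apart after their values were seen. The 2 sets also overlap, with Tagln at 0.77, below Col6a3. Of the 11, 7 had a higher mean in number 3, with Col6a3 at 1.63, Postn at 0.88 and Col1a2 at 0.62, and 4 a lower mean. Of these 4, only the fibroblast proteoglycans Dcn (10.48 and 10.63 against 11.10 to 11.31) and Lum (5.59 and 5.45 against 5.85 to 6.70) were below each other array of the same arm in both arms. Lum and Fbln1 lay below background in both arrays numbered 3. No size of change is read for them, though the median of the 11 includes both. The 25 collagen, matrix and TGF-beta target genes also had a higher mean log2 signal in number 3, at 8.86 against 8.36 and 8.45. The shortfall of the other 11 members argues against an equal rise of all stromal genes as the cause of the whole pattern. A general rise that differs between genes, or a smaller one, stays open. More cells of some stromal kinds, or a change within them, also stay open and untested, since the labels name no difference between the numbers.

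Sertoli cell markers were mostly near background while stromal markers were not. A general failure of hybridisation or RNA is argued against by the respiratory chain and proteasome genes, of which 93.7% (59 of 63) were above background on all 6 arrays. These are bright genes, with list means of 7.70 to 8.72 by sample number, so they do not show how well dimmer transcripts were detected. Other testis cells in the cultures remain a possible explanation: 78.9% of the peritubular myoid and fibroblast markers were above background, with Col1a1 at 11.63, Tagln at 11.35 and Dcn at 10.96 in control arrays. None of those markers is in another list, although cultured Sertoli cells can also make some of them. Whether cells other than Sertoli cells made the Sertoli markers above background was not tested. Insensitive probe sets stay open as well: 1 Sertoli marker had several probe sets, Fshr, at log2 signals of 2.60 and 10.62, but the brighter one lies outside the gene and is annotated with GAPDH transcripts too, so their disagreement decides nothing. A loss of Sertoli transcripts in culture was not tested.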
